A study of Mus musculus with 8 samples.

How the data were processed

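The series holds 8 ChIP-seq samples of mouse embryonic fibroblasts. There is 1 library for each of 3 antibodies (STAT1, STAT2, IRF9) in WT and in Arid1a-knockout cells, and 1 input library per genotype. Peak lists of the 6 antibody libraries were analysed, and the 2 inputs were not analysed here. Groups were taken from the sample titles. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication and libraries were made with a commercial DNA kit.

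Per the submitters' processing notes, STAR 2.5, HOMER 4.8 and the mouse genome build mm10 were used, with no role given for each. Per the file headers, each list was written by the peak annotation program of HOMER from the peak file of a single library, so peaks were called per library and not on pooled samples. The peak-calling settings, the treatment of duplicate and multiply mapping reads and the use of the inputs are not given in the sources used here. Per the file headers, the deposited values of a peak are its position in mm10, a peak score, a focus ratio, its annotation, its distance to the nearest transcription start site (TSS) and the nearest gene. The peak score is the authors' own value. Within each list all scores below 40 were whole multiples of 1 step, within the rounding of the file, as tag counts scaled to a common total would be. The scale itself is not stated. The focus ratio, deposited by the authors as a fraction from 0 to 1, had medians of 0.753, 0.800 and 0.806 in the WT STAT1, STAT2 and IRF9 lists and of 0.739, 0.800 and 0.800 in the KO lists. Scores were used to describe, rank and filter peaks within a list. The alternatives with a score minimum applied to several lists assume that these have the same scale.

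The depth of the libraries is known only in relative terms. The steps were 0.709, 0.534 and 0.674 for STAT1, STAT2 and IRF9 in WT and 0.650, 1.12 and 0.610 in KO cells. Library totals are not known. If 1 step is 1 tag, which is an assumption, the lowest score of each list stands for 9, 13 and 11 tags in WT and 9, 7 and 10 tags in KO cells. Median scores were 9.93, 11.8 and 13.5 in WT and 9.74, 15.6 and 11.6 in KO cells. Under that assumption many peaks of each list rest on few tags, and their presence or absence is imprecise.

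Peaks were compared with bedtools 2.31.1. A peak was called shared when a peak of the other list overlapped it by at least 1 bp. Chance overlap was described by 1000 seeded random placements of a list within each peak's chromosome. Fewer placements were used for the overlap of peaks found in a single genotype with the peaks of another antibody. Each chromosome ended 100 kb beyond its last gene, since chromosome lengths were not used here. Random placement ignores that open chromatin is easier to precipitate. A site with all 3 antibodies was a STAT2 peak overlapped by a STAT1 and an IRF9 peak of the same genotype. A gene had a peak when a peak within 5 kb of a start site named it as the nearest gene. Only the nearest gene is named, so at a shared promoter, such as that of Tap1 and Psmb9, the other gene is not counted.

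Peaks were matched to genes of the GRCm38.p6 annotation, the same build as mm10, by Entrez identifier, and 99.7% to 100% of the peaks in a list matched. The background was 21900 protein-coding genes. There were 12 gene lists, of which 6 hold interferon-regulated genes (antiviral effectors, signalling and feedback, nucleic acid sensing, antigen presentation, interferon-inducible GTPases, chemokines and cytokines). The others hold fibroblast and matrix, immediate early and AP-1, ribosomal protein and BAF complex genes, macrophage and leukocyte markers, and epithelial and endothelial markers. Mx1, Mx2, H2-T10, Gbp11 and Cxcl11 are not protein-coding in this annotation and were left out of the lists. The number of members with a peak was set beside 10000 random lists of the same size. Shares have exact Clopper-Pearson 95% intervals. With 1 library per group no test across replicates was possible, so no p-value is given.

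The gene lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to have been chosen later. For each antibody the rule takes the 10 peaks of highest score within 5 kb of a start site among KO-only, shared and WT-only peaks. It adds the highest peak of each library, up to 10 sites with all 3 antibodies per genotype, and any member of a fixed list with a peak. The genes named for sites with all 3 antibodies and no WT peak are also named by this rule, but that group was formed after the values had been seen. Alternatives were the upper part (50%) of each list by score, lists of equal length, a larger overlap, a distance between centres, another distance to the start site, and the removal of peaks on chromosome Y, the mitochondrial genome and unplaced sequences. The planned search for ISRE and GAS motifs under the peaks needs the genome sequence and was not run. The overlap and gene list computations were tested on simulated data, where all 200 planted shared peaks were found for each antibody. Of 200 random gene lists per library, at most 8 lay above the 95th percentile. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.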

Results

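Chromatin binding of STAT1, STAT2 and IRF9 was profiled by ChIP-seq in mouse embryonic fibroblasts (MEFs) that were wild type (WT) or lacked Arid1a (KO). Arid1a encodes a DNA-binding subunit of the BAF chromatin remodelling complex. STAT1, STAT2 and IRF9 together form ISGF3, the transcription factor complex that type I interferon receptors activate. The series title places the comparison in a study of how ARID1A restrains STING and type I interferon signalling, and the labels name no interferon or other stimulus. Each genotype and antibody had 1 library with 1 peak list, which gave 6 lists, and the 2 input libraries were not analysed here. A peak list does not measure the product of Arid1a, and no list had a peak within 5 kb of its start site, so the knockout itself cannot be checked here. No difference between genotypes has a replicate check, and no p-value was computed. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

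The lists held 1514 STAT1, 614 STAT2 and 388 IRF9 peaks in WT cells, and 2014 STAT1, 1720 STAT2 and 1189 IRF9 peaks in KO cells. All peaks of a list had the same width, and the covered length was 262, 106 and 66.3 kb in WT and 340, 298 and 203 kb in KO cells. Library totals are not in the peak lists, but the low scores of each list were whole multiples of a single step, which stands for 1 tag if the scores are scaled tag counts. Those steps give the KO library 1.09 times the depth of the WT library for STAT1, 0.478 times for STAT2 and 1.10 times for IRF9, provided that both lists were scaled to the same total. The peak of highest score lay at the promoter of Rtp4 in the STAT1 and IRF9 lists of both genotypes. In the STAT2 lists it lay at the promoter of Irf9 in WT and of Bst2 in KO cells. Rtp4 encodes a chaperone for receptors, and Bst2 encodes tetherin, which holds budding virus particles at the cell surface.

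The first comparison asked how many sites each factor occupied with and without Arid1a. STAT2 and IRF9 had more peaks in KO than in WT cells, with ratios of 2.80 and 3.06, and STAT1 had 1.33 times as many. With only the peaks of score 20 or more, a minimum that was chosen after the lists had been seen and assumes the same score scale in all of them, the ratios were 1.26 for STAT1, 3.62 for STAT2 and 2.55 for IRF9. If 1 step is 1 tag, a STAT2 score of 20 stands for fewer tags in KO than in WT cells, where the steps were 1.12 and 0.534. The STAT2 difference in peak number went against the implied depth, which was lower in the KO library if both lists were scaled to the same total. KO-only STAT2 peaks of high score lay at the promoters of Slfn9 (chromosome 11, 82991774 to 82991946, score 131.8), of the MHC class I gene H2-D1 (chromosome 17, 35262862 to 35263034, score 127.3) and of Gm12250 (chromosome 11, 58183686 to 58183858, score 116.1). Further ones lay at the start sites of Etv6, Oas3, Oasl1 and H2-K1, with scores of 99.4, 83.8, 82.6 and 79.3. KO-only IRF9 peaks included the promoters of Tor3a, Slfn9, Gm12250, the cytokine signalling inhibitor Socs1, Cmtr1 and Pml, with scores from 59.2 to 92.1. The highest KO-only IRF9 peak near a start site, with a score of 106.1, lay between Tap1 and Psmb9 on chromosome 17 (34187596 to 34187766), in the shared promoter region of a peptide transporter gene and an immunoproteasome gene. KO-only STAT1 peaks were led by the promoters of Tor3a (chromosome 1, 156674370 to 156674538, score 79.9), Uba7 (39.6), Tgtp2 (37.7), Tdrd7 (37.7), Iigp1 (35.7) and Dhx58 (34.4) and by a peak in the first intron of Daxx (55.2). A KO-only STAT1 peak of score 40.3 at the Irf2 promoter was assigned to the neighbouring Gm16675.

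Peaks of the strongest interferon targets were present in both genotypes. By a minimum overlap of 1 bp, 433 of the 614 WT STAT2 peaks (70.5%, interval 66.7 to 74.1) were overlapped by a KO STAT2 peak. The same held for 277 of the 388 WT IRF9 peaks (71.4%, 66.6 to 75.8) and 460 of the 1514 WT STAT1 peaks (30.4%, 28.1 to 32.8). In 1000 random placements on the same chromosomes the number never passed 5. Among KO peaks, the shared part was 22.8% for STAT1, 25.2% for STAT2 and 23.3% for IRF9. The shared STAT2 peaks of highest KO score were at the promoters of Bst2, Irf9, Ifi27, Rtp4, Stat2, Mx2, Shisa5 and Irgm1, in the 5' UTR of Oasl2 and in intergenic sequence upstream of Stat1 (539.4) and near Mir1932 (493.6). At Bst2 (chromosome 8, 71537496 to 71537668 in KO) the STAT2 peak had score 727 in the KO list and 333.9 in the WT list. Peak scores are the authors' own, and a higher score in the list of one genotype does not show more binding there. Shared IRF9 peaks were led by Rtp4, Oasl2, Usp18 and Bst2, and Isg15 and Ddx60 were among the first 10. Usp18 encodes the protease that removes ISG15 from proteins and dampens interferon receptor signalling.

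**Figure D1:**
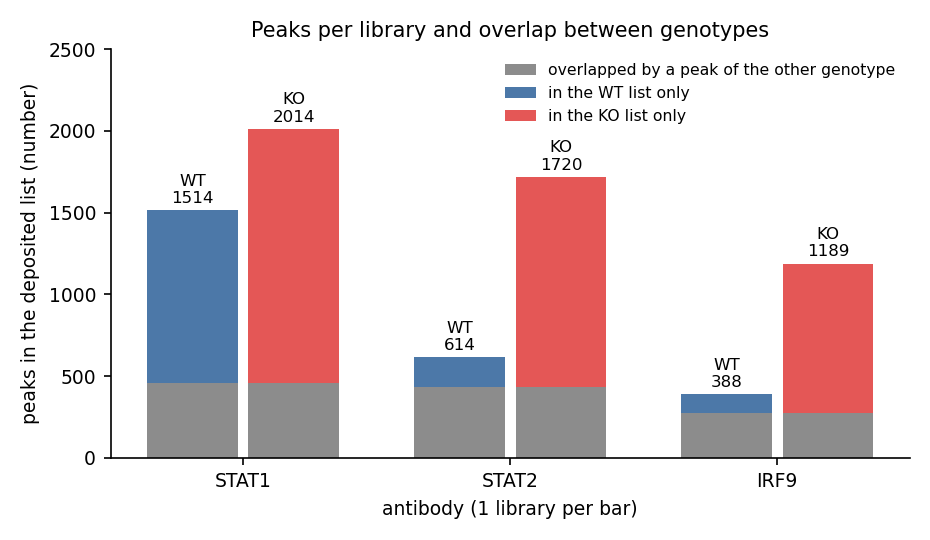
Number of peaks in each deposited list (vertical axis) for the 3 antibodies, 1 library per bar, with the part overlapped by a peak of the other genotype in grey and the rest in blue (WT) or red (KO). The STAT2 and IRF9 lists are longer in KO cells (1720 against 614, and 1189 against 388), and most WT peaks of these factors are grey, which is not so for STAT1.

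The shared part depended on the score. With each list divided into 4 classes of nearly equal size by score, 96.8% of STAT2 peaks (92.6 to 98.9), 97.9% of IRF9 peaks (92.7 to 99.7) and 57.8% of STAT1 peaks (52.6 to 62.8) in the highest WT class had a KO counterpart. In the lowest class the values were 43.1%, 41.2% and 16.4%. Among KO peaks, the highest class was shared at 67.2% for STAT2, 66.8% for IRF9 and 50.4% for STAT1, and the lowest at 2.79%, 3.37% and 9.74%.

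**Figure D2:**
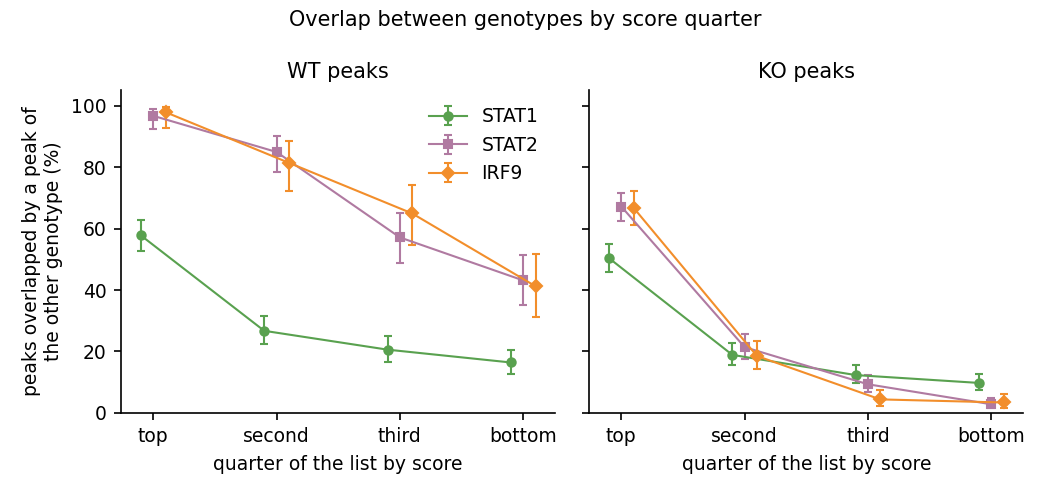
Percent of peaks overlapped by a peak of the other genotype (vertical axis), by 4 score classes of nearly equal size from the highest to the lowest (horizontal axis), for WT peaks (left) and KO peaks (right); points are single libraries and bars are exact 95% intervals. WT STAT2 and IRF9 peaks go from 96.8% and 97.9% in the top class to 43.1% and 41.2% in the bottom one.

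WT-only peaks were mostly STAT1 peaks. There were 1054 of them for STAT1, 181 for STAT2 and 111 for IRF9. The WT-only STAT1 peaks of highest score near a start site lay at Add1 (chromosome 5, 34573579 to 34573751, score 70.2, at a start annotated to Mir7036b) and at the promoters of Irf1 (chromosome 11, 53769849 to 53770021, score 63.1), Klhdc10 (chromosome 6, 30401746 to 30401918, score 61.0), Cox18 (49.6) and Cep41 (42.5). Irf1 encodes a transcription factor that is a classical STAT1 target in the interferon-gamma response. In KO cells no list had a peak at the Irf1 promoter. All 3 KO lists had a peak upstream of the gene, at Mir7671, from 53762935 to 53763107 in the STAT2 list (score 91.6), and no WT list had one there. WT-only STAT2 peaks had lower scores and included the Stat1 promoter (32.1), a peak in the first intron of Ifit2 (32.1) and the Ghitm promoter (19.8). WT-only IRF9 peaks were led by the promoters of Zfas1 (42.4), Ino80 (25.6) and Ghitm (23.6).

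Stat1 itself, a target of ISGF3, carried an upstream peak in every list and a promoter peak in the WT lists only. An intergenic peak 5526 to 5596 bp upstream of the start site (chromosome 1, 52113793 to 52113965 in the WT STAT2 list) was found with all 3 antibodies in both genotypes. Its scores for STAT1, STAT2 and IRF9 were 143.9, 245.2 and 102.4 in WT and 196.2, 539.4 and 239.7 in KO cells. A second peak at the Stat1 promoter (52119269 to 52119441 in the WT STAT2 list) was listed in WT cells only, with scores of 30.5, 32.1 and 16.2. The promoter peak was one of 8 WT sites with all 3 antibodies that no KO peak overlapped.

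**Figure D3:**
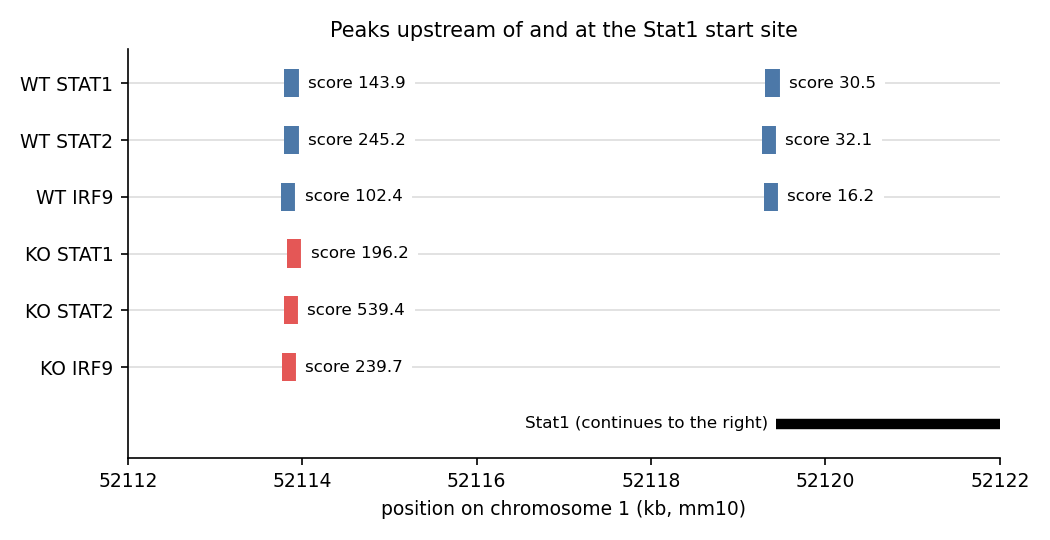
Map of the peaks around the Stat1 start site (horizontal axis, position on chromosome 1 in kb, mm10), 1 row per library, WT in blue and KO in red, with the score of each peak and the start of the Stat1 gene in black. The upstream peak stands in all 6 libraries and the promoter peak in the 3 WT libraries.

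The next comparison asked where the 3 factors met, since sites with all 3 antibodies are those where ISGF3 could be bound. In WT cells 190 STAT2 peaks were overlapped by both a STAT1 and an IRF9 peak, and in KO cells 461 were, a ratio of 2.43. With each list shortened by score to the length of the shortest of all 6, the ratio was 1.57. Of the WT sites, 148 were also sites with all 3 antibodies in KO cells. Both genotypes had Irf9, Bst2, Rtp4, Ifi27, Stat1 (the upstream peak), Stat2, Shisa5 and Oasl2 among their first 10. Another 144 of the KO sites had no WT peak of any antibody, and 97 of those lay over 5 kb from a start site. By STAT2 score they were led by the promoters of Slfn9, Gm12250 and Etv6, followed by Mir7671 and an intron of Ms4a4d. In WT cells STAT1 met STAT2 at 273 peaks, STAT2 met IRF9 at 259 and STAT1 met IRF9 at 216, and in KO cells the numbers were 600, 810 and 518. IRF9 peaks were overlapped by STAT2 peaks at 66.8% in WT (61.8 to 71.4) and 68.1% in KO cells (65.4 to 70.8). STAT1 peaks were overlapped by STAT2 peaks at 18.0% in WT (16.1 to 20.1) and 29.8% in KO cells (27.8 to 31.8). In 1000 random placements no pair of antibodies met at more than 3 peaks.

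Peaks found in a single genotype differed in how often another antibody marked them. Of the 1287 KO-only STAT2 peaks, 35.0% (32.4 to 37.6) were overlapped by a KO IRF9 peak, and of the 912 KO-only IRF9 peaks 61.0% (57.7 to 64.1) by a KO STAT2 peak. For WT-only peaks the values in the WT lists were 12.2% (7.78 to 17.8) and 32.4% (23.9 to 42.0). KO-only STAT1 peaks were overlapped by a KO STAT2 peak at 23.1%, and WT-only STAT1 peaks by a WT STAT2 peak at 7.02% (5.55 to 8.73). KO lists are longer, which raises such shares, and the lists of 1 genotype may share an input, so that part of an overlap may come from it.

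Interferon-regulated genes had peaks far more often than random genes in all 6 lists. Of 164 genes in 6 lists fixed beforehand, 67 had a STAT1 peak, 78 a STAT2 peak and 70 an IRF9 peak within 5 kb of the start site in WT cells. In KO cells the numbers were 67, 94 and 86. Protein-coding genes of any kind with such a peak numbered 602, 263 and 184 in WT and 712, 630 and 444 in KO cells. The rise in STAT2 and IRF9 peaks was thus not particular to interferon-regulated genes, whose numbers rose by a smaller factor. None of 10000 random lists of 164 protein-coding genes held more than 16. A core of 53 genes had a peak in all 6 lists, among them Isg15, Ifit2, Ifit3, Rsad2, Usp18, Irf7, Irf9, Stat2, Cxcl10 and B2m, and 61 genes had none in any list. With any antibody, 84 genes had a peak in WT and 98 in KO cells. The 19 genes with a peak in KO lists and none in WT lists included Oas3, Oasl1, Isg20, H2-D1, H2-K1, Psmb8, Psme1, Psme2, Sting1 and Tbk1. The 5 genes with a peak in WT lists and none in KO lists were Irf1, Irf3, Sp110, Stat1 and Tnfsf10. Stat1 is among them because its upstream peak lies beyond 5 kb. Irf3, Sp110 and Tnfsf10 each had a peak in a single WT list, with scores of 8.51 (STAT1), 8.08 (IRF9) and 10.8 (IRF9). These lay below the median scores of their lists, 9.93 for STAT1 and 13.5 for IRF9. Some of the 19 KO-only genes were as weak. Sting1, Gbp10, Sp100 and Mndal had only a STAT2 peak, with scores of 11.2, 13.4, 13.4 and 10.1 against a KO median of 15.6. Ifit1bl1 had only an IRF9 peak, with a score of 7.93 against a KO median of 11.6. The other KO-only genes each had at least 1 peak above the median of its list. Where both lists of an antibody were shortened to equal length, the KO surplus was 8 genes for STAT2, against 16 with the full lists. For STAT1 the difference was 0 with the full lists and took either sign under the alternatives.

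**Figure D4:**
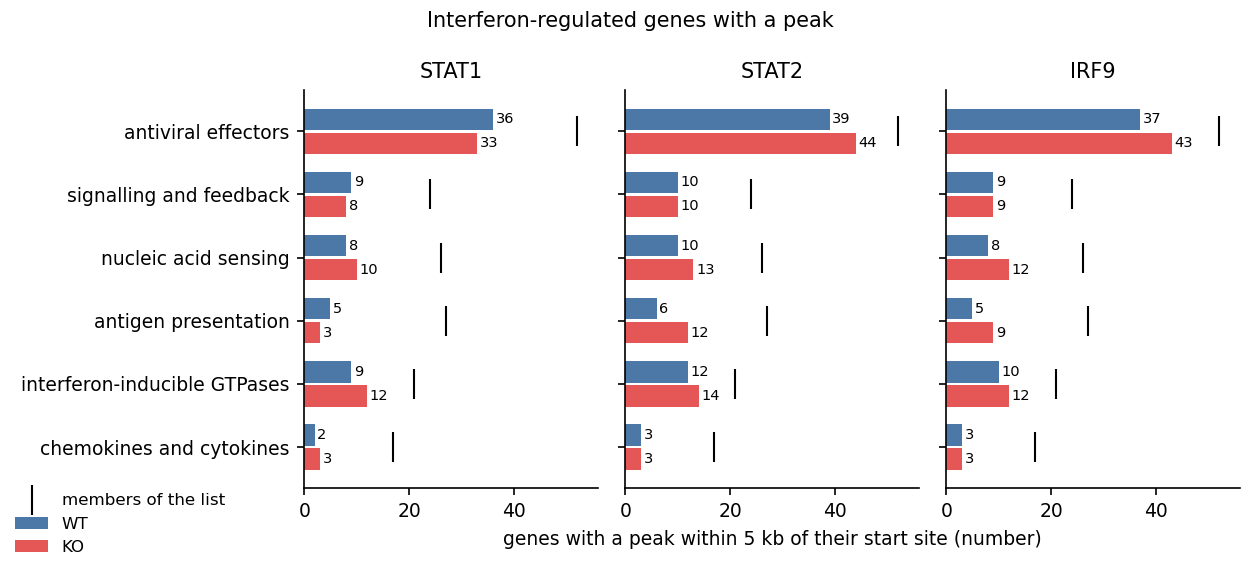
Number of genes with a peak within 5 kb of their start site (horizontal axis) in each of the 6 interferon-regulated gene lists, for the 3 antibodies (panels), with WT in blue, KO in red, 1 library per bar, and a black tick at the number of list members. Antigen presentation has 6 WT and 12 KO genes for STAT2, and 5 and 3 for STAT1.

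Antiviral effectors were the most fully occupied group. Of 52 members, 36, 39 and 37 had a STAT1, STAT2 or IRF9 peak in WT cells, and 33, 44 and 43 in KO cells. Oas3 (chromosome 5, 120777638 to 120777810), which makes the second messenger of the RNase L pathway, had KO promoter peaks of score 83.8 for STAT2 and 41.5 for IRF9 and none in WT cells. Oasl1 and the exonuclease gene Isg20 likewise had STAT2 and IRF9 peaks in KO lists and none in WT lists. Ifit1bl2 was counted as KO-only and Ifit1 as WT-only for STAT2, but both names stand for overlapping peaks between these neighbouring genes on chromosome 19. With this site counted as shared, 17 interferon-regulated genes were KO-only and 1 was WT-only for STAT2. In the STAT1 lists 5 members had a peak in WT only (Apol9b, Ifi35, Lgals3bp, Nmi and Trim21), and Helz2 and Tor3a had one in KO only. The Ifit, Oas and Phf11 families hold near-identical copies, and how reads that fit several copies were treated is not given in the sources used here, so which copy was bound is uncertain.

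Of 27 antigen presentation genes, 6 had a STAT2 peak in WT and 12 in KO cells, and 5 and 9 had an IRF9 peak. Protein-coding genes of any kind with a peak rose as well, from 263 to 630 for STAT2 and from 184 to 444 for IRF9. For STAT1 the numbers of antigen presentation genes were 5 and 3, and they stayed so with equal length and within 1 kb. They were equal in both genotypes with the upper part of the lists (3) and with peaks at any distance (6). The KO-only STAT2 genes were the class I heavy chain genes H2-D1 and H2-K1, the class I-like gene H2-M3, the immunoproteasome gene Psmb8 and the proteasome activator genes Psme1 and Psme2. Psme2 (chromosome 14, 55590914 to 55591086 in the STAT2 list, score 36.9) was the only member with a peak in all 3 KO lists and in no WT list. Its STAT1 peak (55591334 to 55591502, score 10.4) did not overlap its STAT2 or IRF9 peak, so this was not a site with all 3 antibodies. B2m, the light chain of class I molecules, had a peak in all 6 lists, with STAT2 scores of 66.2 in WT and 192.1 in KO cells. Tap1 had a STAT2 peak in both genotypes and an IRF9 peak in KO cells only. The STAT1 peaks at Erap1, Psmb10 and Tapbp were found in WT cells only, with scores of 8.51, 9.22 and 17.7. Those at Erap1 and Psmb10 lay below the median score of the list (9.93). The class I genes are similar in sequence, which leaves their assignment uncertain in the same way.

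Nucleic acid sensing genes had STAT1, STAT2 and IRF9 peaks at 8, 10 and 8 of 26 members in WT and at 10, 13 and 12 in KO cells. Sting1, which encodes the adaptor that relays cytosolic DNA sensing, had a promoter STAT2 peak in KO cells (chromosome 18, 35740496 to 35740668). Its score of 11.2 put it at rank 1392 of 1720, and it was not among the upper part of the list tested as an alternative. Zbp1, a sensor of Z-form nucleic acids, had a STAT2 peak in both genotypes and an IRF9 peak of score 57.3 in KO cells only. Tbk1, the kinase downstream of STING, had KO peaks for STAT1 (7.15, in the first intron) and IRF9 (15.9, at the promoter), and neither was in the KO list shortened to the WT length. With such lists, nucleic acid sensing genes with a STAT2 peak numbered 10 in both genotypes. Cgas, Trex1, Mavs, Ifnb1 and the RNase H2 genes had no peak within 5 kb in any list. The RNA sensor genes Ifih1 and Tlr3 had one in all 6 lists, and Ddx58 in all except KO STAT1.

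Of 24 signalling and feedback genes, 9, 10 and 9 had a STAT1, STAT2 or IRF9 peak within 5 kb in WT and 8, 10 and 9 in KO cells. With peaks at any distance the numbers were 10, 11 and 10 in WT and 11, 16 and 14 in KO cells. Irf7, Irf9, Stat2, Usp18, Ube2l6, Herc6 and Cd274, which encodes PD-L1, had peaks in all 6 lists. Interferon-inducible GTPases had peaks at 9, 12 and 10 of 21 members in WT and at 12, 14 and 12 in KO cells. Every member with a peak in WT cells also had one of the same antibody within 5 kb in KO cells, though not always at the same place. No KO STAT2 peak overlapped the WT one at Gbp2 (score 13.9), and the KO peak counted there lay further upstream (score 39.1). Iigp1 and Tgtp2 had a STAT2 peak in both genotypes and STAT1 and IRF9 peaks in KO cells only. Of 17 chemokine and cytokine genes, 2 had a STAT1 peak within 5 kb in WT and 3 in KO cells. In each genotype 3 had a STAT2 peak and 3 an IRF9 peak. For IRF9 only 2 of the genes were the same, with Tnfsf10 in WT only and Ccl5 in KO only. With the upper part of the lists 1 gene had an IRF9 peak in WT and 3 in KO cells. At any distance 4 had a STAT1 peak in each genotype, 3 had a STAT2 peak in WT and 7 in KO cells, and 3 and 6 had an IRF9 peak. Cxcl10 and Il6 were in all 6 lists. Ccl5 had an intergenic STAT2 peak upstream of its start site in both genotypes, joined in KO cells by STAT1 and IRF9 peaks.

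Lists unrelated to interferon gave few peaks, though not all of them lay in the middle of the random lists. Among 10000 random lists, the BAF genes in KO cells stood at percentile 95.5 for STAT1 and 96.9 for STAT2, and the immediate early genes at 96.0 in WT and 96.2 in KO cells for STAT2. The lowest percentiles of interferon lists were 92.3 for chemokines and cytokines in WT STAT1 and 94.1 for antigen presentation in KO STAT1. Of 31 fibroblast and matrix genes, 3 had a STAT1 and 1 a STAT2 peak in WT cells, against 1 STAT1, 2 STAT2 and 1 IRF9 peak in KO cells. Of 26 immediate early and AP-1 genes, 1, 2 and 1 had a STAT1, STAT2 or IRF9 peak in WT and 1, 3 and 1 in KO cells. Junb was the nearest gene of a peak in 5 of the 6 lists, which lay at the end of the neighbouring gene Prdx2. Of 35 ribosomal protein genes, 2 had a STAT1 peak in each genotype, 1 had a STAT2 peak in KO cells and none had an IRF9 peak. Of 24 genes of BAF and related complexes, 1, 1 and 0 had a peak in WT and 3, 3 and 1 in KO cells. Arid1a had no peak within 5 kb, while Arid1b and Arid2 had 1 KO peak each, for STAT1 (12.3) and STAT2 (16.8). No member of the 22 macrophage and leukocyte markers or of the 17 epithelial and endothelial markers had a peak in any list.

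The last comparison asked where in the genome the peaks lay. A smaller part of KO than of WT peaks lay within 1 kb of a start site. For STAT2 it was 34.0% in WT (30.3 to 37.9) and 25.9% in KO cells (23.8 to 28.0), and for IRF9 38.7% (33.8 to 43.7) and 26.2% (23.7 to 28.8). For STAT1 it was 32.2% (29.8 to 34.6) and 26.9% (24.9 to 28.9). The shared STAT2 and IRF9 peaks were near start sites at 38.1% and 41.9%, and KO-only ones at 21.8% (19.5 to 24.1) and 21.4% (18.8 to 24.2). Of KO-only STAT2 peaks 40.6% lay in introns and 39.5% between genes, and of shared ones 33.7% and 30.9%. The order was different for STAT1, where WT-only peaks were near start sites at 33.5% (30.6 to 36.4), shared ones at 28.7% (24.6 to 33.1) and KO-only ones at 26.3% (24.1 to 28.6). Sites with all 3 antibodies lay within 1 kb at 51.6% in WT and 30.4% in KO cells. When both lists of an antibody were shortened to the same length, the STAT2 and IRF9 values in KO cells were 38.3% and 41.2%, no longer below those in WT cells.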

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

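The tests of explanations for the STAT2 peak number, the unshared STAT1 peaks and the Stat1 promoter were chosen after the results had been seen, and the alternatives given for gene lists were planned. In 3 gene lists the difference between genotypes went in opposite directions for different antibodies. Antiviral effectors had 3 fewer members with a peak in KO than in WT cells for STAT1 (a difference of -3), and 5 more for STAT2 and 6 more for IRF9. Antigen presentation genes had a difference of -2 for STAT1, 6 for STAT2 and 4 for IRF9. Fibroblast and matrix genes had a difference of -2 for STAT1, 1 for STAT2 and 1 for IRF9. For antiviral effectors 34 WT and 33 KO members had a STAT1 peak with the upper part of the lists by score, and 37 and 36 with peaks at any distance. The numbers were 36 and 33 with equal length and 35 and 32 within 1 kb. The STAT1 difference for antigen presentation was 0 with the upper part and at any distance. With equal length and within 1 kb the numbers stayed at 5 WT and 3 KO members. For fibroblast and matrix genes 6 WT and 9 KO members had a STAT1 peak at any distance. The other alternatives gave 3 and 1 with equal length, 2 and 0 with the upper part and 2 and 1 within 1 kb. These differences between antibodies were not tested, because each rests on 1 library per genotype.

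A deeper KO library as the reason for the excess of STAT2 peaks in KO cells (1720 against 614) is argued against by the score steps, which imply a depth of 0.478 times that of the WT library if both were scaled to the same total. Calls scattered by chance, as the source of all the added peaks, are argued against by the overlap with IRF9. A KO IRF9 peak overlapped 35.0% of KO-only STAT2 peaks (450 of 1287), where no random placement, of fewer than 1000 made, passed 0.155%. That overlap does not bear on the KO-only STAT2 peaks without an IRF9 peak, for which chance calls remain open. Background regions common to the KO lists, through a shared input for example, remain open. Stronger enrichment throughout the KO precipitation remains open as well. It predicts that added peaks are weak, and 2.79% of the lowest of 4 score classes of KO STAT2 peaks were shared against 67.2% of the highest. This cannot decide the question, because weak peaks of the longer list would be shared less often under other explanations too. Not all added peaks were weak, as 289 of 430 peaks in the highest class (scores of 30.2 or more) were shared and the rest were KO-only. More ISGF3 binding without ARID1A could give the same picture and was not tested, as it would need replicate libraries.

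Most STAT1 peaks of one genotype had no counterpart in the other. Peaks near the calling threshold, found in one library and missed in the other, could account for part of this. Of the lowest of 4 score classes of WT STAT1 peaks 16.4% were shared, and of the highest 57.8%. This fall cannot decide the question, because weak peaks would be shared less often under other explanations too. In the highest class (scores of 13.5 or more) 219 of 379 peaks were shared and the rest were WT-only. Peaks near the threshold do not account for all of the unshared peaks. A score of at least 30 was reached by 20 WT-only STAT1 peaks, in a list whose lowest score was 6.38. A difference in STAT1 binding between the genotypes, or between the cultures used, remains open for those. Background of the 1 WT STAT1 library remains open too, as 16 of the 20 were in no other list and the inputs were not analysed.

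The Stat1 promoter peak was in the 3 WT lists and in no KO list. A caller that drops a weaker peak next to a much stronger one could hide it, as the upstream peak, 5526 to 5590 bp from the start site in KO cells, had a high score. The highest ratio of any peak to a weaker neighbour within 6 kb was 3.56, 12.6 and 6.39 in the KO STAT1, STAT2 and IRF9 lists. These lie below the ratios of 6.43, 16.8 and 14.8 that a promoter peak with its WT score would have, if the lists share a scale, so no listed pair excludes a hidden peak. At the ratios within the WT lists (4.72, 7.64 and 6.32) the KO STAT2 and IRF9 lists do hold such pairs and the KO STAT1 list does not, and since the ratio in KO cells and the caller's rule are not known, loss of binding cannot be told apart from a hidden peak.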

How the results depend on the processing

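The score minimum of 20, the common score minimum and the sites defined without STAT1 were chosen after seeing the data. No paired analysis was possible because each genotype and antibody had 1 library, and for the same reason no library could be left out. The planned motif alternatives were not run, since the genome sequence was not used here. Library totals are not known and depth was not varied, so how far it limits the lists was not tested. The KO surplus of interferon-regulated genes with a STAT2 or IRF9 peak stayed above 0 under all alternatives run. The ratio of KO to WT peak counts is 1 with equal list length and keeps its value with the upper part of each list, both by construction. Under a common score minimum it was 1.31 for STAT1, 3.32 for STAT2 and 2.69 for IRF9.

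The percent of WT peaks shared with KO cells moved with the list used. With the upper part of each list by score it was 36.5 for STAT1, 88.9 for STAT2 and 89.2 for IRF9. With equal length it was 27.1, 56.5 and 57.5, by construction, as the KO list is shortened. With an overlap of 50% of both peaks it was 24.8 for STAT1 and 64.5 for STAT2. KO sites numbered 810 with STAT2 and IRF9 alone, against 259 in WT cells, and the ratio of sites with all 3 antibodies was 1.57 with equal length. The KO minus WT difference in interferon-regulated genes for STAT1, which was 0, became 4 with the upper part of the lists, -1 with equal length, -2 within 1 kb, 6 at any distance and 8 with scores of at least 20. For STAT2 it was 8 with equal length and 26 at any distance, and for IRF9 27 with scores of at least 20. The cause was not tested.

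The percent of peaks within 1 kb of a start site was higher with the upper part of the lists, at 42.0, 48.2 and 52.6 in WT and 34.0, 33.6 and 34.8 in KO cells (STAT1, STAT2, IRF9). With equal length it was 29.5, 38.3 and 41.2 in KO cells. Within 5 kb, a wider definition, it was 43.6, 47.9 and 53.9 in WT and 39.3, 41.5 and 42.4 in KO cells. Among the main results, such as peak counts and shared percents, 91 values stayed the same and 35 moved. Among single lists and genes, 601 values stayed the same and 89 moved. Both counts include the removal of peaks on chromosome Y, the mitochondrial genome and unplaced sequences. That removal took at most 2 peaks from a list and could hardly move a value. Sting1, Sp100, Mndal, Ifi203 and Gbp10 lost their KO-only STAT2 peak with the upper part of the lists and with equal length. Stat1 had a peak in both genotypes at any distance, through its upstream peak.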

Other observations

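Of the 18 interferon-regulated genes with a STAT2 peak in KO cells only, 17 had no WT peak of STAT1 or IRF9 either. The exception was Ifit1bl2, whose site was named Ifit1 in the WT STAT2 list. There was little room for another outcome, since 84 of the 164 genes had a WT peak of any antibody and 78 had a WT STAT2 peak. A WT STAT1 peak was found at 67 genes and a WT IRF9 peak at 70, so the shares that follow are not comparable with this one. Of the 12 genes with a STAT1 peak in KO cells only, 10 already had a STAT2 or IRF9 peak in WT cells, among them Dhx58, Uba7, Tor3a, Iigp1, Tgtp2 and Ccl5. Of the 19 genes with an IRF9 peak in KO cells only, 11 had a STAT1 or STAT2 peak in WT cells, such as Tap1, Socs1, Pml and Zbp1. In the other direction, 9 of the 12 genes with a STAT1 peak in WT cells only kept a STAT2 or IRF9 peak in KO cells. At the promoters of Ifi35, Lgals3bp, Trim21 and Ddx58 both factors remained listed while the STAT1 peak was not.

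The 20 WT-only STAT1 peaks with scores of at least 30 formed a group chosen after its values were seen. Of these, 12 lay within 1 kb of a start site, 4 were overlapped by a WT STAT2 or IRF9 peak, 3 by a KO STAT2 or IRF9 peak, and 16 were in no other list. Apart from Irf1, Stat1 and Lgals3bp they were not in the interferon lists, and they included the promoters of Add1, Klhdc10, Cox18, Cep41, Prpf40b, Cabin1 and Chchd6.

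Cxcl10, which encodes a chemokine that draws T cells, had a pair of peaks in all 6 lists. One lay at the promoter (chromosome 5, 92348971 to 92349143 in the KO STAT2 list, score 79.3). The other lay 4708 bp upstream, in the second intron of Art3 (92353511 to 92353683).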
